A study of Mus musculus with 12 samples.

How the data were processed

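The series profiled mouse embryonic fibroblasts (MEFs) by chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which DNA bound by a protein is pulled down with an antibody and sequenced. Per the labels, USF2, a transcription factor of the basic helix-loop-helix leucine zipper class, was precipitated from wild-type cells in normal culture and after glucose starvation, with 2 libraries per condition. Of the 12 samples of the series, 4 are these USF2 libraries. The input libraries and the libraries for H3K27ac, a histone mark of active promoters and enhancers, from Usf2 wild-type and knockout cells were not analysed here.

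Each USF2 library came with its own peak list, so replicates were called separately and not pooled. The submitters' processing notes name Bowtie2 2.5.1, MACS2 2.2.7.1 and deepTools 3.5.1 and the build GRCm38, without parameters. Whether the inputs served as control in peak calling is not stated there. In the deposited lists each peak has a fold enrichment, a ratio of the read pileup at its summit to the local background as computed by the authors' peak caller. The deposited −log10 p and −log10 q values are those of the same caller, and the deposited score is 10 times −log10 q cut to a whole number. The highest q-value in the deposited lists was 0.0499. A fold enrichment depends on the depth and settings of its library, so it was used to describe, rank or filter peaks within a list, and no fold change between lists was computed from it. Values of several lists were combined where regions are ordered for naming, by their smallest fold enrichment over the lists that call them, and where the 2 lists of a condition set a fold bound or tertile. For regions of all 4 lists this order mixes lists of different depth and width and does not compare binding between them. A region missing from a list did not pass the caller's threshold there, which is not a measurement of absent binding.

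The narrowest peak was 152 bp wide in both normal lists and 306 bp wide in both starved lists, so the lists of the 2 conditions were made with different widths. The read pileup and local background behind each peak were recovered from its fold enrichment and p-value, as the whole number of reads k with fold (k + 1)/(background + 1) whose Poisson tail matched −log10 p best. All peaks matched within 0.001 on the −log10 scale. On simulated peaks rounded the same way, the true pileup came back for 99.8% of 1956 peaks. The lowest background of each list corresponded to 644.0 and 644.1 reads per Mb in the normal libraries and to 428.4 and 434.1 in the starved libraries. The starved libraries thus had 0.670 times the background read density of the normal ones. The median pileup at a summit was 5 and 6 reads in the normal lists and 8 and 6 in the starved lists, which limits the precision of any single weak peak.

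Peaks on chromosomes 1 to 19, X and Y were merged into regions where they overlapped by at least 1 bp, and a region was called in a list when a peak of that list was part of it. Its summit was that of its peak with the highest −log10 q. Genes came from the NCBI RefSeq gene table of GRCm38.p6, which is the build of the lists. It gives start and end of 21887 protein-coding genes on these chromosomes but neither strand nor exons, so promoters could not be told from the far ends of genes, and exonic, intronic and UTR positions are not given. The planned distance to a transcription start was therefore replaced by a summit within 1000 bp of either end of a protein-coding gene, called a gene-end region. No genome sequence was used here, and the planned counts of the E-box, the DNA motif of USF proteins, were not run.

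List sizes were compared by an exact two-sided permutation test over the 6 labelings of the 4 lists. Overlap was described by the Jaccard index, the number of shared regions divided by the number in either list. Region counts specific to a condition were set beside the other 2 ways to split the 4 lists into pairs. Gene-end shares were compared with 100000 random positions between the first and last gene of each chromosome by two-sided Fisher exact tests. For 17 gene lists the share of members with a gene-end region was compared with that of all other protein-coding genes by two-sided Fisher exact tests with Benjamini-Hochberg adjustment over the lists. The same test asked whether list members called in both normal lists were also called in a starved list, for lists with at least 5 such members. Intervals are 95% exact intervals and cover counting error only. On simulated data the region step returned the planted call pattern for all 3000 regions, and the list test found 100% of 50 planted lists and 0% of 800 unchanged ones. Planted lists had a far higher share of called genes than the rest, and unchanged lists held random genes. This check does not measure the power for smaller differences or the effect of regions shared by neighbouring genes.

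The gene lists, tests and alternatives were fixed before the data were examined, except those said to be added later. The comparison of gene-end shares between conditions was added in place of the E-box comparison, and the list test on regions of one condition alone and the overlap without identical peak edges were added after the data were seen. Alternatives were a stricter q or fold, another overlap rule, lists cut to equal length, other distances and backgrounds, the replicate number as a block, and leaving out each library. Most genes and regions are named by a rule. It takes the 10 regions with the highest smallest fold enrichment among those called in all 4 lists, in both normal lists alone and in both starved lists alone, each with the nearest gene within 5000 bp. It adds up to 4 members per gene list called in both normal lists, by the smaller of the 2 normal fold enrichments, and a set of 12 genes named whatever their result: Usf1, Usf2, Tfeb, Tfe3, Mitf, Lamp1, Ctsd, Mcoln1, Sqstm1, Map1lc3b, Ulk1 and Fasn. Not every region or gene that the rule takes is reported. Named outside the rule, after their values were seen, are the lysosomal list members with a region of one condition alone, the members of symbol groups and Sirt1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.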

Results

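USF2 binding was profiled in wild-type MEFs, fibroblasts grown from mouse embryos, under normal culture and after glucose starvation. There were 2 libraries per condition, and the labels do not say whether they came from separate cultures, so the spread between them may be technical. The normal libraries gave 1645 and 2124 peaks and the starved libraries 825 and 1178 peaks on the assembled chromosomes. Merged over the 4 lists these made 3804 regions. Coordinates below are those of GRCm38.

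The strongest USF2 site in each of the 4 lists lay at the start of the annotated span of Lamp1, which encodes a major protein of the lysosomal membrane. This region (chromosome 8, 13158740 to 13159419) had its summit 15 bp from the gene end, and its fold enrichment was 47.0 and 44.1 in the normal lists and 25.5 and 32.3 in the starved lists. Altogether 247 regions were called in all 4 lists, and 205 of them, or 83.0% (95% exact interval 77.7 to 87.5), were gene-end regions. Several of the strongest belonged to lysosomal and endosomal genes. Nagpa, an enzyme that uncovers the mannose 6-phosphate signal of lysosomal enzymes, had a region on chromosome 16 (5203464 to 5204292) with fold enrichments of 18.5, 18.5, 18.5 and 16.5 in the order normal 1, normal 2, starved 1 and starved 2. In the same order, Atp6v0b, a subunit of the proton pump that acidifies lysosomes, had values of 21.6, 22.4, 16.1 and 17.2 (chromosome 4, 117886984 to 117887598). Washc2 and Washc5, subunits of the endosomal WASH complex, had smallest fold enrichments of 16.9 (chromosome 6, 116207725 to 116208298) and 15.6 (chromosome 15, 59373912 to 59374522). Further regions among the 10 strongest shared ones lay at Stmn1 (microtubule regulator), Fam118b, Rcbtb1 and Dvl2 (Wnt signalling), with smallest fold enrichments of 17.6, 16.7, 15.1 and 14.4. The regions at Washc5, Fam118b and Dvl2 also lay within 1000 bp of an end of Nsmce2, Rpusd4 and Phf23.

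**Figure D1:**
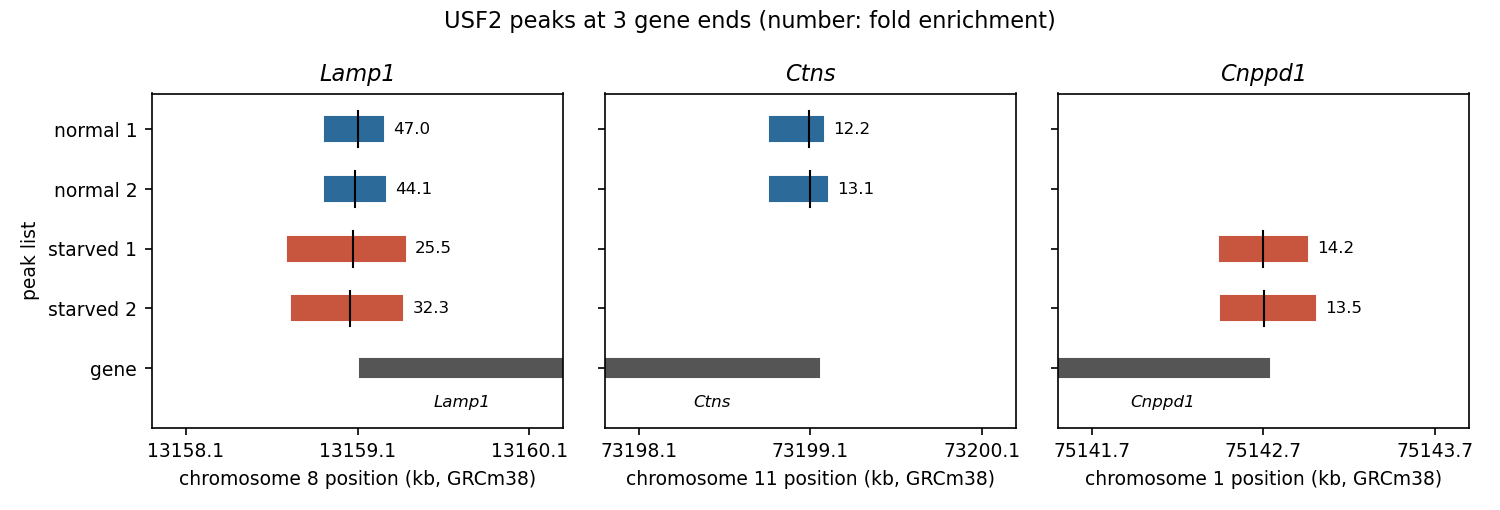
Peaks of the 4 lists (bars, with the summit as a black line and the fold enrichment beside them) around 3 gene ends, with position in kb on the horizontal axis, one row per list and the gene's annotated span in grey. Lamp1 has a peak in all 4 lists, Ctns in the normal lists alone and Cnppd1 in the starved lists alone, and the starved peaks are wider.

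The 3 lists of lysosomal genes were those enriched for USF2 regions at gene ends. Of 58 genes of the lysosomal membrane and trafficking list, 20 had a gene-end region in both normal lists (34.5%, against 2.11% of other protein-coding genes; odds ratio 24.4, 95% interval 13.3 to 43.3; Fisher exact test, adjusted p = 6.78e-18). Beside Lamp1 they included Clcn7, a lysosomal chloride/proton exchanger (fold enrichment 18.5 and 18.0 in the normal lists), Slc36a1, a lysosomal amino acid transporter (17.5 and 18.5), Hps1, needed for lysosome-related organelles (17.0 and 16.4), and Mcoln1, a lysosomal calcium channel (12.7 and 12.0). Of 56 lysosomal hydrolases and cofactors, 14 had such a region (25%; odds ratio 15.2, 95% interval 7.63 to 28.7; Fisher exact test, adjusted p = 1.08e-10). They included Ctsa (cathepsin A, 30.1 in both normal lists), Nagpa and Ctsb (cathepsin B, 17.6 and 16.9), and the cathepsin D gene Ctsd had 5.65 and 6.90. The summit of the region at Ctsa (chromosome 2, 164833441 to 164834040) lay 896 bp from a Ctsa end and also within 1000 bp of an end of Neurl2. Likewise, the region at Atp6v0c lay within 1000 bp of an end of Amdhd2. Of 18 subunits of the vacuolar ATPase, the lysosomal proton pump, 6 had a region (33.3%; odds ratio 22.5, 95% interval 6.90 to 65.1; Fisher exact test, adjusted p = 9.18e-06), among them Atp6v0b, Atp6v0e (15.0 in both normal lists), Atp6v0c (13.9 and 15.1) and Atp6v1c1 (11.03 and 9.65). Neighbouring genes can share a region, so the 481 genes with a region in both normal lists rest on fewer regions (395), and genes are not independent replicates. The other protein-coding genes include groups without any call, such as the olfactory receptors (0 of 1110), which raises these odds ratios. The activity of genes in these cells was not taken into account. Among genes with a gene-end peak in any list, the question is another one, since the normal lists enter both this set and the outcome: which genes with a peak have one in both normal lists. There 14 of the 17 hydrolases were called in both normal lists, against 53.99% of other genes, and 6 of 6 vacuolar ATPase subunits, against 54.2%. Neither list passed that test (Fisher exact test, adjusted p = 0.196 for both, odds ratio 3.97 for the hydrolases), while the membrane and trafficking list did (odds ratio 5.75, adjusted p = 0.0203). For the vacuolar ATPase 6 of 6 is the highest count possible, so its small size limits what this test can show.

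The other 14 lists did not pass the test against all other protein-coding genes, to which the values below belong. Autophagy genes had 1 region among 48 members, at Atg3, which conjugates LC3 (8.05 and 7.91; Fisher exact test, adjusted p = 1). Amino acid sensing and mTORC1 had 2 of 36, Lamtor1, a lysosomal anchor of mTORC1 (10.9 and 10.1), and Flcn (5.47 and 7.29; Fisher exact test, adjusted p = 0.398). The ER and integrated stress response had 2 of 32, the transcription factor Atf4 (13.6 and 13.0) and its target Chac1 (7.36 and 6.31; Fisher exact test, adjusted p = 0.398). The circadian clock had 2 of 22, Cry1 (8.43 and 8.19) and Tef (7.67 and 8.12; Fisher exact test, adjusted p = 0.284). Ribosome biogenesis and translation had 3 of 32, Eef2 (13.3 and 13.0), Rrn3 and Fbl (Fisher exact test, adjusted p = 0.139), and the cell cycle and DNA replication had 2 of 35, Cdk4 (15.9 and 13.1) and Mcm2 (12.3 and 7.25; adjusted p = 0.398). No member was called in both normal lists for AMPK and the glucose starvation response, glycolysis and glucose transport, lipid and cholesterol synthesis, mitochondrial respiration, basic helix-loop-helix leucine zipper factors, NuRD and histone deacetylation, fibroblast markers or tissue genes of other cell types (Fisher exact test, adjusted p = 1 for each of these 8 lists). The genes of USF2's relatives Usf1, Tfeb, Tfe3 and Mitf, and Sqstm1, Ulk1 and Fasn, had no gene-end peak in any list. Usf2 itself had a gene-end peak in normal 1 alone (fold enrichment 5.46), and Map1lc3b, the gene of the autophagosome protein LC3B, in starved 1 alone (8.05). Regions at Atg3, Lamtor1 and Usf2 also lay within 1000 bp of an end of Slc35a5, Tomt and Lsr. Away from gene ends, both normal lists had a peak inside Usf1 (fold enrichment 4.51 in both; chromosome 1, 171414315 to 171414543; 3179 bp from an end), normal 2 one inside Tfeb (6.07) and starved 1 one inside Fasn (4.38; 1055 bp from an end).

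**Figure D2:**
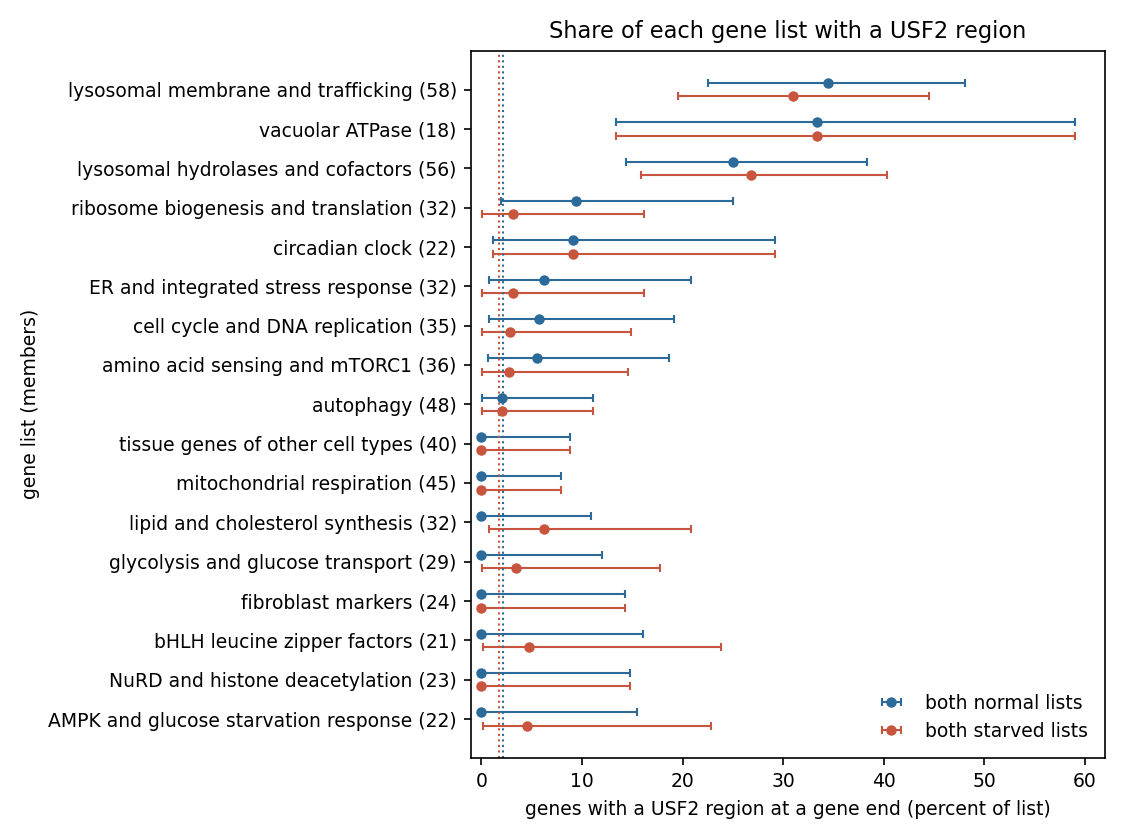
Percent of the members of each gene list with a USF2 region at a gene end (horizontal axis) in both normal lists (blue) and in both starved lists (red), with 95% exact intervals, one row per list with its number of members. Dotted lines mark the mean share of other genes. The 3 lysosomal lists lie between 25% and 34.5% in both conditions.

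The lysosomal lists also led after glucose starvation. Of the membrane and trafficking genes, 18 were called in both starved lists (31.0%; odds ratio 25.8, 95% interval 13.8 to 46.5; Fisher exact test, adjusted p = 9.70e-17), as were 15 hydrolases (26.8%; odds ratio 20.8, adjusted p = 3.40e-13) and the 6 vacuolar ATPase subunits of the normal lists (odds ratio 27.8, adjusted p = 2.79e-06). No other list passed. In all 4 lists 15, 12 and 6 members of these lists were called. Of the 481 genes with a region in both normal lists, 297 (61.7%) had one in at least 1 starved list, and this share was 41.6% in the lowest and 81.2% in the highest tertile of normal fold enrichment. All 14 hydrolases kept a call, against 60.6% of other genes (Fisher exact test, adjusted p = 0.00405 over 3 lists), as did 15 of 20 membrane and trafficking genes (against 61.2%, adjusted p = 0.248) and 6 of 6 vacuolar ATPase subunits (against 61.3%, adjusted p = 0.130). When a call in both starved lists was required, all 3 lists passed, with 12 of 14 hydrolases against 51.0% of other genes (Fisher exact test, adjusted p = 0.0379), 15 of 20 membrane and trafficking genes against 51.0% and 6 of 6 vacuolar ATPase subunits against 51.4% (adjusted p = 0.0403 for both). The hydrolase difference did not pass when genes were stratified by tertile of normal fold enrichment (Mantel-Haenszel chi-square test, adjusted p = 0.0537), although all 14 members kept a call and the odds ratio stayed infinite. The membrane and trafficking list had a stratified odds ratio of 1.25 (Mantel-Haenszel chi-square test, adjusted p = 0.919). The vacuolar ATPase did not pass there either (Mantel-Haenszel chi-square test, adjusted p = 0.366), with all 6 members kept. Calls required in both starved lists were not stratified by normal fold enrichment. Without starved replicate 2 the hydrolase difference did not pass, with 12 of 14 hydrolases kept against 53.5% of other genes (odds ratio 5.19, Fisher exact test, adjusted p = 0.0510).

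Regions called in both lists of one condition alone (1035 over the conditions) outnumbered the 247 called in all 4 lists. Both normal lists and neither starved list called 760 regions, of which 155 (20.4%, 95% exact interval 17.6 to 23.4) were gene-end regions, and both starved lists and neither normal list called 275, of which 106 (38.5%, 32.8 to 44.6) were. The size and the order of these counts depended on the setting. Without normal replicate 1 or 2 the normal-only count was 1765 or 1339, and without starved replicate 1 or 2 the starved-only count was 823 or 540, since 1 list then decides for its condition. Without regions with an identical peak edge, a setting added later, 351 normal-only and 197 starved-only regions were left. With every list cut to its 825 best peaks there were 207 normal-only and 219 starved-only regions, with −log10 q of at least 5 there were 182 and 99, and with summit pileups of at least 10 reads 121 and 111. Under these settings all 4 lists called 215, 170 and 203 regions, against sums of 426, 281 and 232 for the conditions alone. The 2 peaks of a region had an identical start or end coordinate in 53.8% of the 760 and 28.4% of the 275 regions. In pairs of lists across conditions this share lay between 0.291% and 1.12% of shared regions, where the peak widths differ. Splitting the lists by replicate number gave 2 and 51 such regions and the crossed split 3 and 3. With 3 possible splits an exact p cannot fall below 0.33.

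Among normal-only regions the highest smallest fold enrichment (20.1) was in Rab21, a gene of an endosomal GTPase (chromosome 10, 115315526 to 115315753), with the summit 1805 bp from a gene end and 1 peak edge identical in the 2 lists. It was followed by 5730455P16Rik (19.8; chromosome 11, 80377917 to 80378156), Rad54l2 (16.9; chromosome 9, 106789125 to 106789356), Camk2d (13.2), Commd4 (13.2), Cetn3 (12.9), Vps51, a subunit of endosomal tethering complexes (12.7; chromosome 19, 6077155 to 6077396), Fra10ac1 (12.6), a region outside genes on chromosome 8 (107268644 to 107268895; 12.4), and Ctns, the lysosomal cystine transporter (12.2; chromosome 11, 73198832 to 73199161; also an end of Shpk, and likewise with an identical edge). Ctns, Gga2, Tmem192, Vps16 and Vps35 were the 5 membrane and trafficking genes with a normal-only region (8.62% of 58, against 0.829% of other genes; Fisher exact test over the 17 lists, added after the data were seen, adjusted p = 0.00227), and no hydrolase had one. As the list is enriched in the normal lists as a whole, this does not show that its genes lost calls more often, and the other 15 of its 20 genes called in both normal lists kept one. Among starved-only regions the first was at Cnppd1 (13.5; chromosome 1, 75142459 to 75143015), followed by Cbx6, a Polycomb protein gene (12.1; chromosome 15, 79834110 to 79834666), Mapre1 (12.0), Slc38a2, an amino acid transporter (11.9; chromosome 15, 96698618 to 96699155), Rbm15b (10.6), Gclc, the catalytic subunit of glutathione synthesis (10.04; chromosome 9, 77750599 to 77751004, 3732 bp from the gene), Napa (9.80), Ogdhl (9.71), Ccnyl1 (9.40) and Slc16a1, a monocarboxylate transporter (9.27; chromosome 3, 104638189 to 104638650). The hydrolase-list genes Galns, Gnptg and Ppt1 (3 of 56) and the membrane genes Hps3 and Ostm1 (2 of 58) had a starved-only region, and no list passed the same test there (Fisher exact test, adjusted p = 0.0657 and 0.359). Regions at Galns and Gnptg also lay within 1000 bp of an end of Trappc2l and Tsr3. The same held for Vps16 (Pced1a), Vps35 (Orc6), Vps51 (Tmem262), Cnppd1 (Retreg2) and Cbx6 (Npcd), so these regions cannot be assigned to 1 gene. Beside Rab21 and Ctns, an identical peak edge was also found at Tmem192 in the normal lists. In the starved lists it was found at Mapre1, Ccnyl1 and Hps3.

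**Figure D3:**
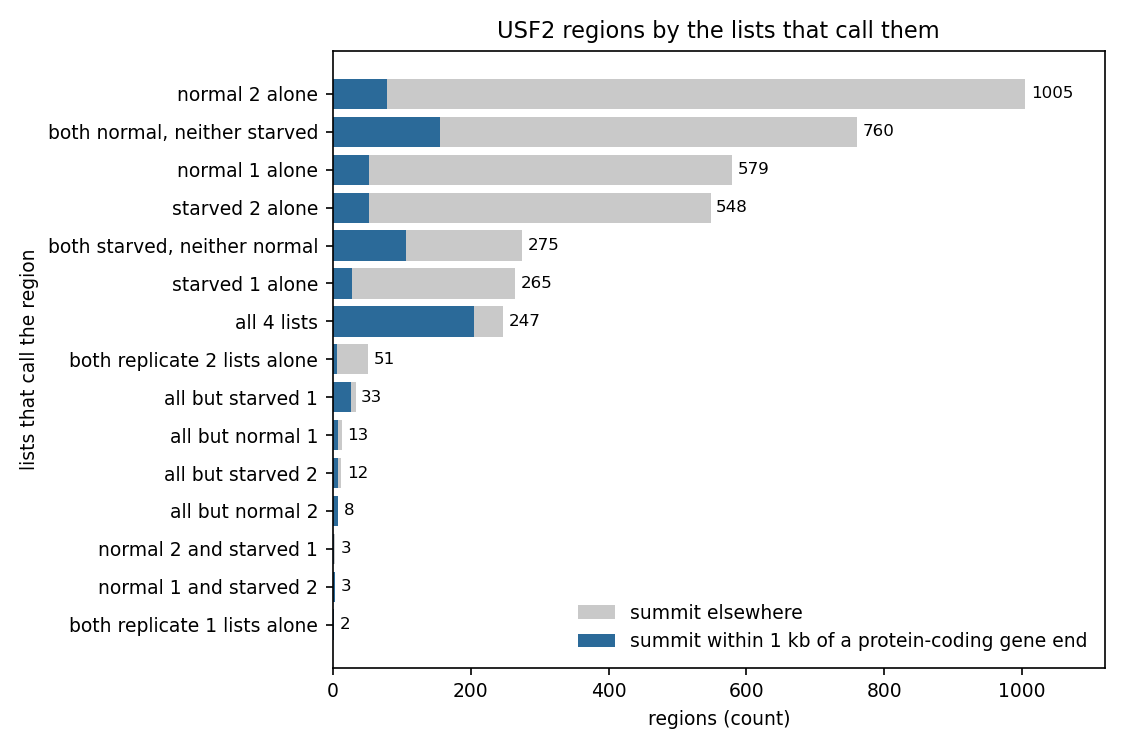
Number of merged regions (horizontal axis) for each combination of lists that call them (rows), with gene-end regions in blue and the rest in grey. Gene-end regions make up 205 of the 247 regions called in all 4 lists and 78 of the 1005 called in normal 2 alone.

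Lists of one condition shared more regions than lists across conditions, which also differ in calling width. The Jaccard index was 0.387 for the normal pair and 0.372 for the starved pair, and between 0.103 and 0.122 for the 4 pairs across conditions. The values across conditions were 0.0483 to 0.0615 with a reciprocal overlap of 50%, 0.172 to 0.206 with the 825 best peaks of each list and 0.224 to 0.302 with −log10 q of at least 5. The 2 peaks had an identical start or end in 44.8% of the regions shared by the normal pair and 21.7% of those shared by the starved pair. Leaving such regions out, which can only lower the index, gave 0.259 for the normal and 0.317 for the starved pair, so the order of the 2 pairs turned (a setting added after the data were seen). The order also turned under a planned setting, −log10 q of at least 5, with 0.473 for the normal and 0.584 for the starved pair. It stayed with the other overlap rules and with the 825 best peaks. For each pair, peaks placed at random between the first and last gene of their chromosome shared at most 3 regions. This placement does not follow the gathering of peaks at gene ends, so it does not measure sharing specific to USF2. A single list called 2397 regions (63.0%), of which between 7.76% and 10.6% per list were gene-end regions.

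The starved lists were 0.527 times as long as the normal lists (geometric means; 1001.5 ± 249.6 against 1884.5 ± 338.7 peaks, SD, n = 2 each). The exact two-sided permutation p was 0.33, the smallest that 2 against 2 lists allow. Depth and calling width also differed between the lists of the 2 conditions. Gene-end regions made up 37.5% of the 1052 regions called in both normal lists (95% exact interval 34.6 to 40.6) and 60.2% of the 543 called in both starved lists (56.0 to 64.4), against 2.93% of random positions (odds ratios 19.9 and 50.1). These odds ratios were 31.9 and 76.1 within 500 bp, 7.34 and 19.7 within 5000 bp, and 11.2 and 28.6 with all annotated genes. Of single peaks, 27.9% and 23.0% in the normal and 44.4% and 35.4% in the starved lists were at gene ends (exact permutation test over lists, two-sided p = 0.33, the smallest possible). The odds ratio over pooled peaks was 1.91. Its Fisher exact p of 1.10e-27 describes these peaks and not the conditions, since peaks of 2 lists are not independent. With every list cut to its 825 best peaks by q, the shares were 43.0% and 44.2% in the normal and 44.4% and 46.1% in the starved lists, and the pooled odds ratio was 1.07 (Fisher exact test, p = 0.381).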

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

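Starved replicate 2 held 8 peaks on 4 unplaced contigs of the assembly, which no comparison used, whereas the other 3 lists held none there. The strongest had a fold enrichment of 10.6 and a recovered pileup of 23 reads. No biological explanation was tested for these peaks.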

How the results depend on the processing

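The settings named as added below were chosen after seeing the data. Of the alternatives to the main counts, tests and ratios, 36 left the result within its spread, within 1.5 times or on its side of the threshold, 17 moved it and 1, the gene-end odds ratio with lists of equal length, ended a call over pooled peaks. The counts that moved include an ended call, that of the hydrolases in the retention test. No single result changed direction, but the order of the normal-only and starved-only counts did with lists of equal length (207 and 219). The order of the Jaccard indices of the normal and starved pairs turned with −log10 q of at least 5 (0.473 and 0.584). It also turned, as an added setting, without regions with an identical peak edge (0.259 and 0.317). The normal-only count of 760 was 182 with −log10 q of at least 5, 207 with the best peaks of each list, and, as added settings, 351 without regions with an identical peak edge and 121 with summit pileups of at least 10 reads. The starved-only count of 275 was 219 with the best peaks of each list, 99 with the stricter q and 111 with the added pileup minimum. Leaving out each library in turn gave 772 to 1765 normal-only and 283 to 823 starved-only regions; the highest counts came without normal replicate 1 and without starved replicate 1, where 1 list decides for its condition. The ratio of the mean Jaccard index within conditions to that across them, 3.33, was 6.62 with a reciprocal overlap of 50%, 2.10 with the best peaks and 1.99 with the stricter q. Lists passing the enrichment test numbered 3, and 1 when the background was genes with a gene-end peak in any list, which holds the lists of the outcome and so does not test enrichment; the vacuolar ATPase and the hydrolases did not pass there (Fisher exact test, adjusted p = 0.196 for both), and the odds ratio of the former was infinite. For the vacuolar ATPase all 6 members in that background were called, which no result could exceed. Lists passing the retention test numbered 1, and 3 when both starved lists had to call the gene, 0 in the Mantel-Haenszel test and 0 to 1 without each starved replicate. In the main retention test all 3 lists had a higher share kept than other genes. There the vacuolar ATPase could not pass, as 6 of 6 kept is the highest count possible (Fisher exact test, p = 0.0870 before adjustment). The odds ratio of gene-end peaks, 1.91, was 1.07 with lists of equal length, an added setting. In each case the cause was not tested.

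The 2 replicate numbers mark no shared batch in the labels. With the replicate number as a block, the ratio of list lengths was 0.527 (exact sign-flip p = 0.50) and the gene-end odds ratio 1.93. The correlation of replicate differences between conditions, over regions, was 0.00206. Most regions (2397 of 3804) were called in a single list, which holds this value near 0, so it cannot exclude a shared batch. Both lists of one replicate number alone called 53 regions, 51 of them in replicate 2, against 6 for the crossed pairs. The E-box settings were not run, because no genome sequence was used here. Low depth limits the precision of weak peaks: 47.3% to 67.4% of the peaks of a list had a pileup of at most 6 reads.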

Other observations

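The tests in this part were all chosen after the results they bear on were seen. Genes were grouped by the letters before the first digit of their symbol, which gave 657 groups of at least 5 protein-coding genes. In both normal lists 5 groups passed a Fisher exact test with Benjamini-Hochberg adjustment, 3 of them by a higher share. These were the WASH complex genes Washc1, Washc2, Washc4 and Washc5 (4 of 5; Fisher exact test, adjusted p = 0.000152), the Commd genes Commd2, Commd3, Commd4, Commd8 and Commd9, whose products take part in endosomal recycling (5 of 10; adjusted p = 0.000152), and 8 of 35 Vps genes of vesicle sorting (adjusted p = 0.000152), some of which are also members of the lysosomal trafficking list. Olfactory receptors (0 of 1110) and predicted genes with Gm symbols (3 of 1329) were called less often than other genes (Fisher exact test, adjusted p = 1.59e-08 and 2.56e-07). In both starved lists the Washc (3 of 5), Hps (3 of 5) and Vps (5 of 35) groups passed with a higher share (Fisher exact test, adjusted p = 0.00912, 0.00912 and 0.0492). The Commd group (2 of 10) did not pass there (Fisher exact test, adjusted p = 0.573), nor did the Hps group in the normal lists (2 of 5; adjusted p = 0.253), and the Hps genes are all members of the lysosomal trafficking list. No group passed among starved-only regions.

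Sirt1, a deacetylase gene of the AMPK and glucose starvation list, ranked 25 of 825 peaks in starved 1 and 10 of 1178 in starved 2 by fold enrichment (14.4 and 15.9). Normal 1 also called it (5.29), and normal 2 did not. Fold enrichments and ranks of lists that differ in width and depth do not measure a change. It was singled out after its values were seen.

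Regions called in one condition alone may partly come from DNA fragments that both libraries of a condition hold. Of the 1035 such regions, 396 had peaks starting at the identical base in both lists, which is 41.0 times the mean of 9.65 per base pair at offsets of 1 to 10 bp. Identical starts or ends were not confined to these regions. Of the 247 regions called in all 4 lists, 20.6% had one in the normal pair and 15.0% in the starved pair. The 2 libraries of a condition may thus not be independent, which bears on every count of regions called in both. The different calling widths and the condition coincide, so they cannot be told apart for weak regions, strong regions or gene ends. Of the regions with a fold enrichment of at least 10 in both normal lists, 17.5% (95% exact interval 11.3 to 25.2) were uncalled in both starved lists, and of those in both starved lists 8.96% were uncalled in both normal lists (3.36 to 18.5). Regions with a fold below 5 in a normal list were uncalled 5.47 times as often as those of at least 10, and the 261 gene-end regions of one condition alone were 32.6 times the 8 of the highest other split.

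Fewer peaks in the starved lists could reflect lower depth, since the background read density was 0.670 times that of the normal lists. Lists whose lowest recovered background, an indirect measure of depth, was within 5% still differed in length by up to 1.43 times. This decides nothing, and the calling width also coincides with the condition. Depth, calling width and glucose starvation thus cannot be told apart in 4 lists.

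The 51 regions called in both replicate 2 lists and in neither replicate 1 list may lie at positions of high local background. Their median local background was 4.78 times the genome-wide level, against 1.61 for the other peaks of those lists, a ratio of 2.97. High background is not particular to them: in normal 2 and starved 2 the medians were 9.09 and 3.83 times that level for these regions and 9.09 and 9.56 times for those called in all 4 lists. Among the other peaks, those called in normal 2 alone or starved 2 alone had medians of 1.38 and 1.17 times that level. The ratio was below the bound of 3 for that explanation. As this bound was set after the results were seen, the ratio decides nothing, and the explanation stays open. No biological explanation was tested, because the labels give replicate numbers no meaning.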
